A study of Mus musculus with 2 samples.

How the data were processed

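Chromatin contacts were measured by Micro-C, a form of Hi-C in which crosslinked chromatin is cut with micrococcal nuclease rather than with a restriction enzyme, so that contacts are resolved close to the level of the nucleosome. The cells were V6.5 mouse embryonic stem cells, a pluripotent line. Per the labels, 2 samples were made, both transfected with a control siRNA reagent (siGLO) at 50 nM and collected 48 hours later. They form 1 group, called siControl. No second condition was analysed here, so no comparison between groups was made.

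The data consist of 1 loop list for the group. Per the submitters' processing notes, the genome build was mm10 and the tools included Juicer 1.5.6. The loop caller, its thresholds and whether the reads of the 2 samples were pooled before calling are not given in the sources used here. The list has no header. Each line gives the positions of 2 anchors, a colour, and 8 numbers. The deposited peak score (column 8) and the deposited regional peak score (column 10) are scores of the loop caller. The deposited value of column 9 is a fraction that behaves like a probability, between 0.964 and 1. The deposited signal in column 15 is the value of the peak pixel of the contact map, and columns 11 to 14 describe its neighbourhood. These meanings were inferred. Column 15 minus 8/9 of column 11 equalled column 13 in every line to within 2.3e-06, so column 11 is the peak pixel minus the mean of its 8 neighbours and column 13 is the mean of the 3 by 3 block. The order of the columns matches the output of the SIP loop caller, which no header or label names. How the authors normalized the contact map before the deposited signal was taken is unknown, as is the read depth. Scores and pixel values are the authors' own and were used only to describe and rank loops within this list.

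Anchor positions were turned into 1-based coordinates. A loop's span is the distance between the midpoints of its 2 anchors. Anchors that shared at least 1 bp were merged. Genes were taken from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, restricted to chromosomes 1 to 19 and X (21631 protein-coding records). That table gives the first and last base of a gene but no strand and no exons. The plan, fixed before the data were examined, was to use transcription start sites. It was replaced by asking whether either end of a protein-coding gene record lay inside an anchor, called here a gene end at the anchor. One of the ends is the start of the gene and the other its end, and the list cannot tell them apart. The planned search for CTCF motifs and their orientation needs a genome sequence and was not run. The list holds no observed or expected counts and no q-values, so the peak score of column 8 took the place of observed over expected counts, with no minimum count, and the planned stricter q-value and other expected models were not run.

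Shares of anchors and loops were set beside 1000 random placements, in which all anchors of a chromosome were moved together around the chromosome by 1 random distance. This keeps widths and spacing. A chromosome's extent was taken from its outermost gene record or anchor. Gene lists (12 lists, 344 distinct genes, written before the data were examined) were set beside 10000 random lists of protein-coding genes of the same size, matched in 5 bins on the number of protein-coding genes within 100 kb. Of 346 entries, 336 matched a protein-coding symbol. Results are given as percentiles with ties shared equally above and below, and a value outside the central 95% (2.5 to 97.5) is called apart from the random lists. With 12 lists, about 0.6 would fall outside by chance. A share of 0 loops is also given the limit of 3 counts of the total. Shares carry Wilson 95% intervals, or exact Clopper-Pearson intervals for gene lists, which cover counting error over the loops or genes of this list only. Medians carry 95% intervals from 1000 resamplings of whole chromosomes. No p-values were computed, since loops and genes are not replicates and the list gives no values per sample. In 5 simulations that planted gene ends at 20% of upstream anchors, the mean counted share was 30.1%. The random placements of these gave 12.6%, and none of these simulations fell in the central range. With no planted signal, 97.5% of 40 simulations fell in the central range. For simulated lists of 30 genes with no planted signal, 98.0% of 200 did. When list members were planted at anchors with a probability of 30%, 4.0% of 200 still did. The simulated loops were placed independently, without merging anchors, and the simulated lists were drawn at random. Clustered anchors and clustered lists were therefore not covered.

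Genes named in the text follow a rule set before the data were examined, except for its ranking. It takes up to 12 pluripotency genes, 8 cohesin and CTCF genes and 3 of every other list with an end at an anchor. It also takes the 10 loops of highest peak score, the 5 longest loops and the 5 merged anchors with most loops. Pairs of list members joined by 1 loop are named as well. Genes were ranked by the highest peak score of their loops. The rule as set ranked genes by enrichment over local background or q-value and, with neither, by number of loops. The list holds neither, and ranking genes and loops by peak score was a change made after the list was seen. Some genes and loops that this rule names are not reported here. Alternatives planned or added were wider anchors (5 kb to each side), genes of every biotype, single pixel sizes, autosomes only, local shifts of 0.5 to 2 Mb, any overlap with the gene record, loops above the median peak score of their pixel size, leaving out the 10 highest peak scores, and other random lists. Alternatives on shares of anchors and loops used 200 placements each. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.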

Results

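Micro-C of V6.5 mouse embryonic stem cells transfected with a control siRNA was represented by 1 list of 4982 chromatin loops for 2 samples of 1 group. A loop here is a pair of genomic intervals (anchors) that the authors' caller found in more frequent contact than their surroundings. The list held no values per sample, so the spread between replicates was not measurable and no difference below was tested against it. The read depth of the samples is unknown. The questions addressed were how large the loops were, where they lay, and which genes lay at their anchors in control-transfected cells, the control state of a study of proteins that act with cohesin, the ring complex that forms loops, on chromosome structure. All coordinates are in mm10.

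Every loop joined 2 sites on the same chromosome, and no pair of loops overlapped at both anchors. The median span was 325 kb (95% interval 310 to 340 kb over chromosomes), with quartiles at 190 and 550 kb. The shortest loop spanned 35 kb and the longest 6700 kb. Loops over 1 Mb numbered 418 (8.39%), and 204 (4.09%) were shorter than 100 kb. Span went with the pixel size at which a loop was listed. The 1265 loops of 5 kb pixels had a median span of 190 kb (175 to 210 kb), the 3047 loops of 10 kb pixels one of 330 kb (320 to 360 kb), and the 670 loops of 25 kb pixels one of 650 kb (600 to 700 kb). These intervals did not overlap. The shortest loops spanned 35, 70 and 175 kb and the longest 1440, 2940 and 6700 kb at 5, 10 and 25 kb pixels. Both ends of the range thus rose with pixel size. The shortest span was the same number of pixels at each size, as a lower limit set in pixels would give. At its lower end, the link of span to pixel size thus followed the pixel itself. The caller's distance limits are not stated, so how far the rest of the link reflects the range searched cannot be told. The median peak score, a score of the caller with no unit, was 4.16, with quartiles at 3.59 and 5.00.

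**Figure D1:**
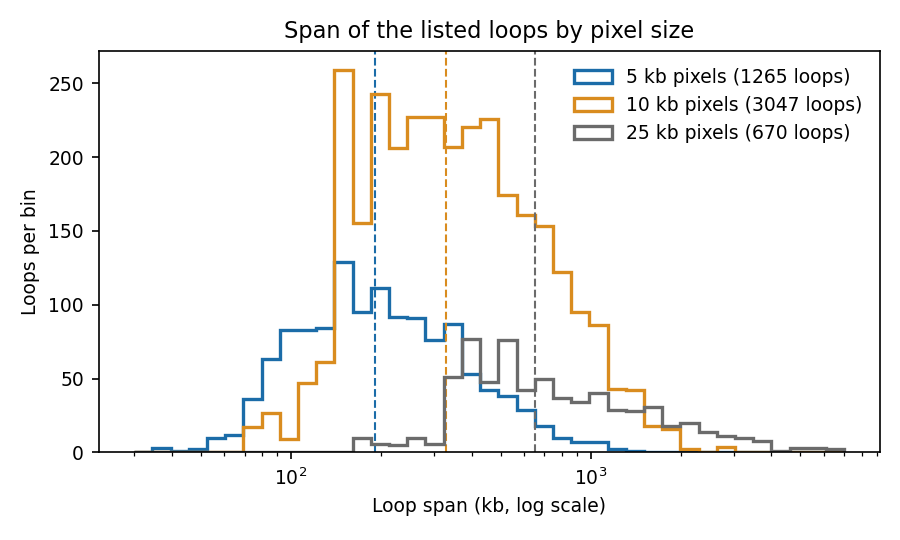
Number of loops (vertical axis) by span in kb (horizontal axis, log scale) for the 5, 10 and 25 kb pixels, with dashed lines at the medians of 190, 330 and 650 kb. Loops of wider pixels had longer spans, and the shortest span was the same number of pixels at each size.

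Loops were unevenly spread over chromosomes. The autosomes together held 1.99 loops per Mb, from 1.33 on chromosome 7 to 2.49 on chromosome 2. The X chromosome, of which these male cells carry a single copy, held 124 loops, or 0.727 per Mb. That is 0.365 times the autosomal density and below every autosome. None of the 124 X loops was of 5 kb pixels. The limit that a count of 0 allows, taken as 3 loops of the 124, is 2.42%, and the Wilson upper limit is 3.005%. At the autosomal density of such loops, 88.4 would have been listed on X. On autosomes 26.0% of loops were of 5 kb pixels. That share ranged from 4.31% (Wilson 95% interval 1.85 to 9.70%) on chromosome 19 to 48.5% (42.8 to 54.2%) on chromosome 11. For 10 and 25 kb pixels alone, the X chromosome still had 0.494 times the autosomal density.

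**Figure D2:**
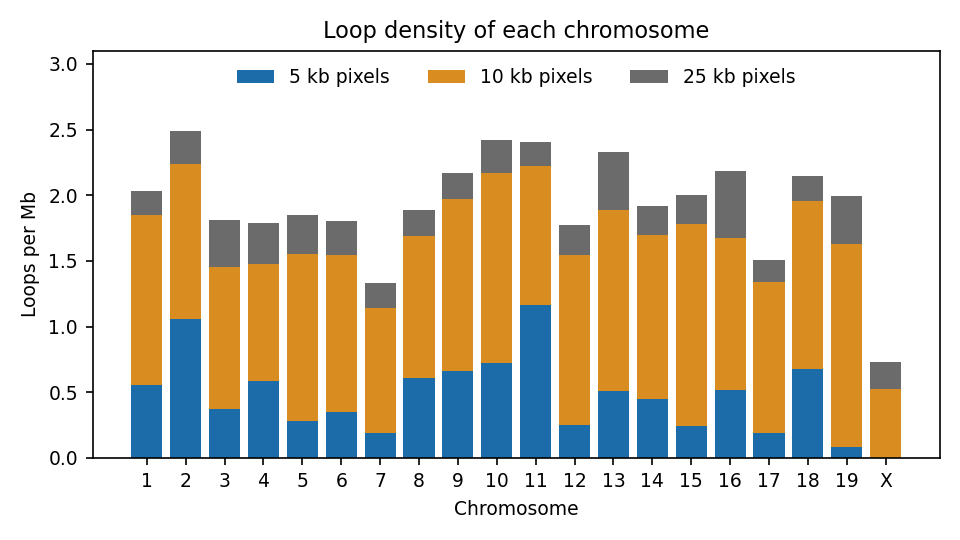
Loops per Mb (vertical axis) on each chromosome (horizontal axis), stacked by pixel size. The X chromosome had 0.727 loops per Mb and no loop of 5 kb pixels, against 1.33 to 2.49 loops per Mb on autosomes.

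Loop anchors lay at gene ends more often than randomly placed anchors did. The 4982 loops had 8740 merged anchors, of which 1721 (19.7%, Wilson 95% interval 18.9 to 20.5%) held an end of a protein-coding gene. Random placements gave a median of 12.8%, and the highest of 1000 gave 14.03%. Gene ends lay at both anchors of 268 loops (5.38%, 4.79 to 6.04%), against 3.08% at random, a ratio of 1.75. They lay at 1 anchor of 1394 loops (28.0%) and at neither anchor of 3320 loops (66.6%). When any overlap with a gene record was counted, the excess was smaller for anchors and gone for loops with genes at both anchors. Of anchors 52.3% then overlapped a gene, against 45.95% at random (ratio 1.14), and 27.6% of loops had genes at both anchors, against 27.4% at random. Peak scores differed little between these classes. The median was 4.09 (95% interval 3.95 to 4.16) with gene ends at both anchors, 4.12 (4.06 to 4.18) with gene ends at 1 anchor, and 4.19 (4.12 to 4.26) at neither. The difference between both and neither was -0.098 (-0.238 to -0.004) over all loops. It was -0.01 (-0.693 to 0.705) among 5 kb pixels and -0.063 (-0.264 to 0.1) among 10 kb pixels, with intervals that span no difference. Among 25 kb pixels it was 0.302 (0.041 to 0.525) in the other direction, so no class was uniformly higher. The pooled value mixes pixel sizes. Loops of 5 kb pixels, whose median score was highest (4.88), were 33 of 268 with both and 924 of 3320 with neither.

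Genes of 4 of the 5 developmental lists lay at loop anchors more often than genes of like surroundings. In the neuroectoderm list, which holds transcription factors of the early nervous system, 14 of 29 genes (48.3%, exact 95% interval 29.4 to 67.5%) had an end at an anchor, against a mean of 12.1% in random lists. The trophectoderm list, of regulators of the placental lineage, had 5 of 12 (41.7%, 15.2 to 72.3%) against 11.025%. The mesoderm list had 6 of 23 (26.1%, 10.2 to 48.4%) against 10.1%, and the Hox list, of the clustered genes that pattern the body axis, had 10 of 39 (25.6%, 13.04 to 42.1%) against 4.17%. The percentiles of these lists among random lists were 100, 99.7, 98.6 and 100, and these 4 of the 12 lists were apart from the random lists. The mesoderm call rested on few genes and was lost with 5 kb pixels alone (8.70% against 2.03%, percentile 95.6), with loops above the median peak score of their pixel size (13.04% against 5.32%, percentile 92.6) and with any gene overlap (34.8% against 20.1%, percentile 95.7). With anchors widened by 5 kb it was at percentile 97.55, but 19 of 20 other random seeds put it inside the central range, so that call is not counted as kept. The trophectoderm call was lost with 5 kb pixels alone, where only 1 of its genes was at an anchor (8.33% against 2.15%, percentile 87.2). In each case the share stayed above the mean of random lists. With any gene overlap the trophectoderm list was at the edge of the central range (percentile 97.655, and 97.46 to 97.86 over 20 other seeds). Eomes belongs to both of these lists. The 10 Hox genes shared 7 merged anchors. When anchors rather than genes were randomised, which keeps the clusters whole, the Hox share itself stood at percentile 99.8, but relative to the share of all genes it stood at 96.4, inside the central range.

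The remaining 8 lists were not apart from random lists, although some alternatives put the protocadherin, imprinted and pluripotency lists apart. The endoderm list had 3 of 17 genes at anchors (17.6% against 11.5% at random, percentile 78.6) and the pluripotency list 6 of 42 (14.3% against 10.7%, percentile 77.8). The imprinted genes had 3 of 25 (12% against 11.9%, percentile 53.6). The protocadherin list, of clustered cell adhesion genes of neurons, had 3 of 30 (10% against 4.13%, percentile 92.1). It does not hold all protocadherins: Pcdhga4, Pcdhgb2, Pcdhga8 and Pcdhgb4, outside it, also had ends at anchors. The imprinted genes stood at percentile 99.0 with 5 kb pixels alone (12% against 2.21%). The protocadherin list stood at 99.96 with anchors widened by 5 kb (26.7% against 7.61%) and at 98.4 with loops above the median peak score of their pixel size. With any overlap of the gene record counted, the list reached 18 of 30 (60% against 5.44%). Random lists break up the protocadherin cluster, in which 1 anchor can count for several genes. With anchors randomised, which keeps the cluster whole, the share of 10% stood at percentile 80.5, and at 74.0 relative to all genes, both inside the central range. The pluripotency share stood at 99.1 with anchors randomised but at 87.8 relative to all genes. The cohesin and CTCF list had 1 of 31 (3.23% against 9.46%, percentile 11.9) and the ribosomal protein list 2 of 46 (4.35% against 7.54%, percentile 22.3). None of 28 housekeeping genes (upper limit 12.3%, against 8.03%, percentile 4.84) and none of 14 markers of fibroblasts, a cell type used as feeders, (upper limit 23.2%, against 10.1%, percentile 11.4) had an end at an anchor. Over all 21631 protein-coding genes the share was 9.04%.

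**Figure D3:**
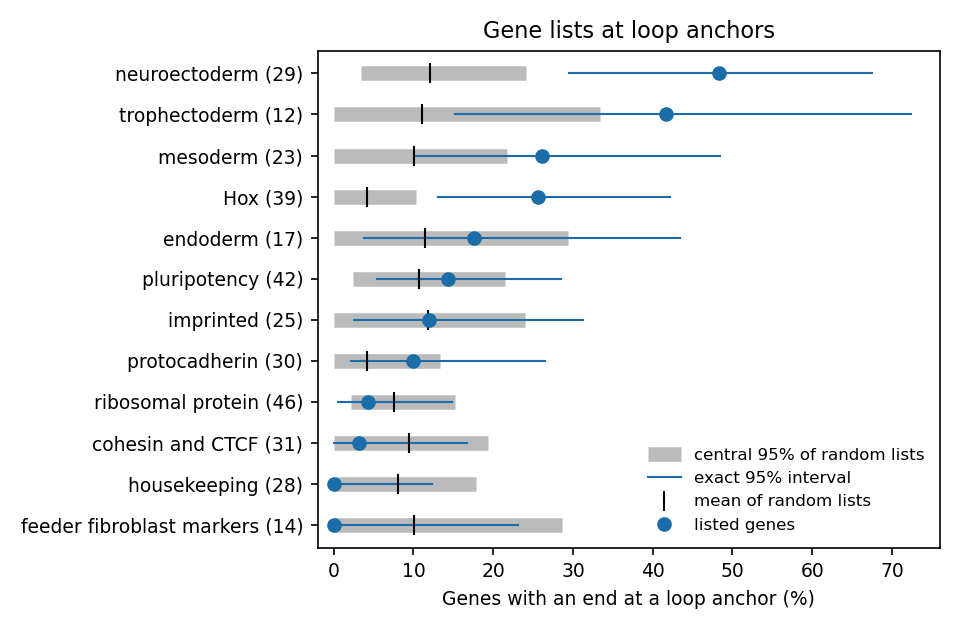
Percentage of genes with an end at a loop anchor (horizontal axis) for 12 gene lists (vertical axis, number of genes in brackets), with points for the list, thin lines for exact 95% intervals, ticks for the mean and grey bars for the central 95% of 10000 random lists. The neuroectoderm list stood at 48.3% against 12.1% at random, and the housekeeping list at 0.

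Of the pluripotency genes, Sox2, a transcription factor that maintains the pluripotent state, had the most loops. Sox2 (chromosome 3, 34649995 to 34652461) was joined to a site 110 kb away, toward higher coordinates (34760001 to 34765000), by a loop of 5 kb pixels with a peak score of 3.79. From an anchor that holds only the outermost bases of the gene record (34640001 to 34650000), 2 loops of 10 kb pixels reached sites 460 kb and 840 kb away, with peak scores of 3.32 and 3.80. No protein-coding gene end lay at the far anchors. The other 5 genes had 1 loop each. Id3, an inhibitor of differentiation, had a loop of 75 kb (peak score 4.35). Klf4, a pluripotency transcription factor, had one of 1160 kb (4.19), and Mycn, a growth-promoting transcription factor, one of 520 kb (4.16). Tbx3 was joined over 1425 kb to an anchor with an end of Spring1 (3.997), and Zfp42 (Rex1), a marker of the naive state, over 1625 kb to one with an end of Fat1 (3.88). The highest peak score of each of these 6 genes lay within the quartiles of all loops. The 36 pluripotency genes without a gene end at an anchor included Pou5f1, Nanog, Klf2, Klf5, Esrrb, Tfcp2l1, Prdm14, Dppa2, Dppa3, Dppa4, Dppa5a, Tdgf1, Lefty1, Lefty2, Nr5a2, Nr0b1, Sall4, Lin28a, Utf1, Fgf4, Fbxo15, Tdh, Stat3, Tcl1, Gbx2, Phc1, Gdf3, Otx2, Dnmt3l, Etv5, Rif1, Spry4, Jarid2, Trim28 and Mycl. Of the cohesin and CTCF list, Pds5a, a regulatory subunit that binds cohesin, had a loop of 290 kb (3.55).

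Some developmental genes were joined to one another over long distances. Irx3 and Irx5, neighbouring homeobox genes on chromosome 8, were the only members of 1 list joined by a called loop. It ran from 91800001 to 91805000 at Irx3 to 92355001 to 92360000 at Irx5, spanned 555 kb, and had a peak score of 6.67. A loop joining members of different developmental lists spanned 3125 kb on chromosome 2, from an anchor with Dlx1 and Dlx2, homeobox genes of the forebrain, and Metap1d (71525001 to 71550000), to an anchor with Hoxd13 and Evx2 (74650001 to 74675000), with a peak score of 9.63. It was seen only when the lists were combined, a step added after the data were examined. The 49 loops with a developmental gene end had a median span of 600 kb (95% interval 325 to 815 kb) and the other 4933 loops one of 320 kb (310 to 340 kb). These intervals overlapped.

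**Figure D4:**
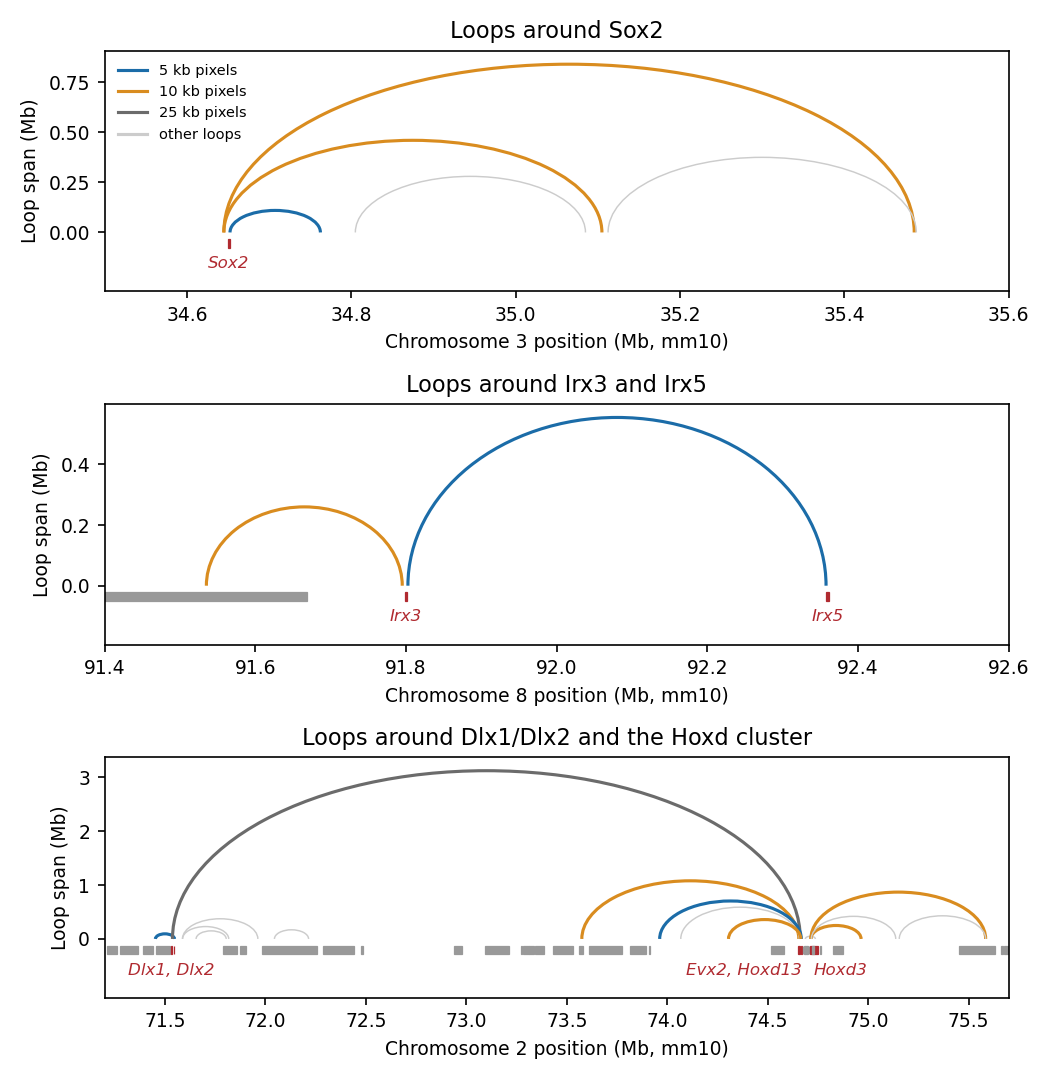
Loops (arcs, height equal to span in Mb) and protein-coding gene records (boxes, named genes in red) by position in Mb around Sox2, around Irx3 and Irx5, and between Dlx1/Dlx2 and the Hoxd cluster. Coloured arcs have an anchor with an end of a named gene, and the longest, at 3125 kb, joined Dlx1 and Dlx2 to Hoxd13.

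The other named developmental genes were picked by the highest peak score of their loops, so their scores do not describe developmental genes in general. The median peak score was 4.23 over all 49 loops with a developmental gene end and 4.16 over the other loops. Foxa2, a transcription factor of endoderm, had 2 loops, of 860 kb (peak score 10.1) and 680 kb (8.28). Foxa1 had 3 loops, the strongest of 850 kb (8.57), and a loop of 1010 kb to an anchor with Nkx2-1 (5.04). Pdgfra, a growth factor receptor, had 2 loops, of 210 kb (5.76) and 350 kb (4.05). Tal1, a regulator of blood formation, had a loop of 880 kb (8.71), and Eomes, which acts in mesoderm and trophectoderm, one of 445 kb (7.15). Hoxa6 had a loop of 1025 kb (9.32) and Hoxd3 had 2, of 870 kb (6.08) and 250 kb (3.90). Gata3 had a loop of 1210 kb (6.27), and Gata2 had 2, with peak scores of 4.03 and 4.06. Among imprinted genes, expressed from 1 parental copy, Magel2 had a loop of 155 kb (7.34), Cdkn1c one of 310 kb (6.63) and Grb10 one of 110 kb (3.91). Among protocadherins, Pcdhb22 had a loop of 340 kb (5.78) and was joined to an anchor with Pcdhga4 and Pcdhgb2 over 170 kb (5.10), and Pcdhb20 to one with Pcdhga8 and Pcdhgb4 over 220 kb (4.13). These Pcdhga and Pcdhgb genes are outside the protocadherin list, so neither loop counts as joining 2 members of 1 list. Pcdha10 had a loop of 220 kb (5.63). Rpl37 and Rpl30 had loops of 1120 kb (6.13) and 2925 kb (5.06).

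Most anchors took part in 1 loop. Of the merged anchors, 1060 (12.1%) had 2 or more loops and 134 (1.53%) had 3 or more. The anchor with most loops (chromosome 3, 113075001 to 113100000) had 7, and the adjoining one (113100001 to 113150000), with an end of the amylase gene Amy2b, had 5. The anchor with Evx2 and Hoxd13 had 5, all running toward lower coordinates, and an anchor with Lsamp on chromosome 16 (42170001 to 42200000) had 5, all running toward higher coordinates. An anchor on chromosome 11 (12520001 to 12550000) with no protein-coding gene end had 4. The 5 longest loops were all of 25 kb pixels. They spanned 6700 kb on chromosome 8 (from Got1l1), 6225 kb on chromosome 13 (to Dimt1 and Ipo11), 6000 kb on chromosome 7 (to Rhcg), 5800 kb on chromosome 3 (from Fubp1 and Nexn to Lrrc40 and Srsf11) and 5325 kb on chromosome 10, with peak scores between 4.11 and 5.90.

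The 10 highest peak scores lay on 4 chromosomes, and the top 3 were far above all others. These 3, of 293, 277 and 194, shared the region from 121320001 to 122650000 on chromosome 4, with an end of the predicted gene Gm12888 at 1 anchor. Another loop there scored 23.7, and a loop from 145550001 to 147525000 on the same chromosome, with an end of Zfp982, scored 32.8. On chromosome 7, loops from an anchor with Cnot3 and Prpf31 to one with Leng8 and Ttyh1, and from the next bin to Eps8l1, scored 40.8 and 35.4. On chromosome 14, loops to Olfr735 and from Olfr736 to Ttc5 scored 36.8 and 21.1. The last was a loop of 1060 kb on chromosome 8 (20.7) with no gene end at its anchors. The peak pixels of the top 3 were ordinary, at percentiles 64.3, 54.0 and 7.55 of 10 kb loops. The loops scoring 40.8, 36.8, 35.4 and 20.7 had peak pixels at percentiles 32.6, 1.64, 73.5 and 42.3 of their pixel size. Those scoring 32.8, 23.7 and 21.1 had peak pixels at 99.9, 88.5 and 98.4. Leaving out these 10 loops changed the shares of anchors and loops with gene ends by less than their counting intervals. So few of the 4982 loops could not have changed them more, so this is no check on the scores.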

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

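No paired analysis was possible because the list gives no values per replicate, and leaving out a replicate was not possible for the same reason. The alternatives on loops above the median peak score of their pixel size, on the 10 highest scores, on any gene overlap, on 5 and 10 kb pixels together, on the regional score, on the placements relative to all genes on random lists without predicted and receptor symbols and on other random seeds were chosen after seeing the data. Not run were stricter q-values, other expected models, 1 start site per gene and CTCF motifs, since the list and gene table lack what they need. Requiring a peak score of at least 2 removed no loop. Of 144 alternative values, 2 reversed, both for the difference in median peak score between loops with gene ends at both anchors and at neither. Its main value of -0.098 was 0.302 at 25 kb pixels and 0.026 with anchors widened by 5 kb. At 5 and 10 kb pixels it was -0.01 and -0.063, and the main value mixes pixel sizes. The cause of the reversals was not tested. A reversal could be counted only for shares of anchors and loops, this difference and the lists apart from random lists. Many of the alternatives could therefore not reverse. With 5 kb pixels only there were 1265 loops with a median span of 190 kb, and with scores above the median 2492 loops with 370 kb, by construction in the counts. The share of anchors with a gene end, and of loops with gene ends at both, was 34.4% and 14.5% with anchors widened (1.61 and 1.93 times random), 33.3% and 12.7% with genes of every biotype (1.40 and 1.59 times), 14.7% and 2.61% with 5 kb pixels (2.08 and 2.54 times), and 52.3% and 27.6% with any gene overlap (1.14 and 1.00 times). Shifting each loop locally gave 1.48 and 1.72 times random. The first of these set merged anchors beside shifted anchors that were not merged, so it compares unlike sets. With 5 kb pixels, the lists had 8.70% (mesoderm, percentile 95.6), 8.33% (trophectoderm, 87.2), 12% (imprinted, 99.0), 4.76% (pluripotency), 0 (cohesin and CTCF) and 0 (ribosomal protein). With scores above the median, mesoderm had 13.04% (percentile 92.6), protocadherin 10% (98.4) and cohesin and CTCF 0. With any gene overlap, mesoderm had 34.8% (95.7), protocadherin 60% (100), cohesin and CTCF 25.8% and fibroblast markers 28.6%, and with anchors widened protocadherin had 26.7% (percentile 99.96) and mesoderm 34.8% at percentile 97.55, which 19 of 20 other random seeds put inside the central range (97.0 to 97.6). With random placements the Hox share of 25.6% stood at percentile 99.8, and at 96.4 relative to the share of all genes, while the protocadherin share of 10% stood at 80.5 and 74.0 and the pluripotency share at 99.1 and 87.8. Over 20 other seeds, the trophectoderm list with any gene overlap was inside the central range with 1. The lowest percentile of the neuroectoderm list under the alternatives run was 99.7 with the reported seed and 99.62 over 20 other seeds. Loops joining 2 members of 1 list numbered 3 with anchors widened, against 1. Anchors with 2 or more loops were 22.2% when merged within 10 kb and 8.35% with scores above the median. Loop positions are no finer than the 5, 10 or 25 kb pixel, and the depth behind each loop is unknown.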

Other observations

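All tests in this part were chosen after the data had been seen, and only for that of the 25 kb anchors was its prediction written before its own result. Beyond anchors, genes were also described by whether a loop enclosed them, with an anchor on either side and none of the gene record in the anchors. Of all protein-coding genes, 32.6% were enclosed. Of the pluripotency list, 24 of 42 genes (57.1%, exact 95% interval 41.0 to 72.3%) were enclosed, against a mean of 36.4% in random lists of like gene density (percentile 99.7). Nanog lay in a loop of 130 kb, Klf2 in one of 105 kb, Prdm14 in one of 80 kb, Lefty1 and Lefty2 in one of 95 kb, and Dppa5a in one of 135 kb as its shortest. Pou5f1 and Otx2 were in none. These examples were chosen after their values were seen. Enclosed shares were also above the random lists for Hox (69.2% against 24.98%), neuroectoderm (65.5% against 39.3%), mesoderm (65.2% against 34.1%) and protocadherin (46.7% against 25.1%). Housekeeping genes were enclosed in 4 of 28 cases (14.3% against 29.5%, percentile 3.29), inside the central range. No enclosed share was tested with anchors randomised. Neighbouring genes, such as Lefty1 and Lefty2 of the pluripotency list, can share loops. The percentiles of enclosed shares are therefore likely too extreme, above all for the clustered Hox and protocadherin lists. By how much was not measured. The random lists were not matched on gene length either, and a short gene record fits more easily between the anchors of a loop. The effect of gene length on the enclosed shares was not measured.

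Several gene families lay at anchors less often than random lists. Of 1110 olfactory receptor genes 22 (1.98%) had an end at an anchor, against a mean of 5.68% in random lists, and of 355 vomeronasal receptor genes 10 (2.82%) did, against 9.43%. Of 1094 predicted genes 38 (3.47%) did, against 9.64%, so the pattern was not particular to receptors. Relative to all genes, these shares stayed low when anchors rather than genes were randomised (percentiles 0, 1.10 and 0). Of the olfactory receptor genes 45.3% were enclosed by loops, against a mean of 26.9% in random lists. This difference was not tested with anchors randomised, and neighbouring receptor genes share loops. These random lists were not matched on gene length. Of 64 replication-dependent histone genes, which lie in clusters, 14 (21.9%) had an end at an anchor, against 4.25% in random lists. With anchors randomised their percentile was 93.8, inside the central range.

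The 4 developmental lists at anchors may reflect a wider property of developmental transcription factor genes. A further 166 transcription factor genes of such families (such as Irx, Nkx, Pax, Sox and Tbx), none of them in the fixed lists, had ends at anchors in 40 cases (24.1%), against 11.1% in random lists. Their percentile was 100 among random lists, and 100 when anchors were randomised. The families were chosen after some of them had been seen at anchors, and symbols of unrelated genes that the family names had matched were removed after the first result, so this set is not independent evidence. Several technical readings were argued against. The lowest of the 4 percentiles was 97.9 (97.75 to 98.2 over 20 other seeds) when predicted, olfactory and vomeronasal symbols were kept out of the random lists, and 98.1 with 25 kb pixels left out. With 5 kb pixels alone, and so fewer loops, mesoderm (95.6) and trophectoderm (87.2) were inside the central range. Hox (99.63) and neuroectoderm (99.945) stayed apart. Anchor width was thus argued against for all 4 lists only as far as 25 kb pixels go. Genes sharing an anchor within a cluster did not account for the neuroectoderm, mesoderm and trophectoderm lists, whose lowest percentile was 98.7 with anchors randomised and shares taken relative to all genes, but stayed open for Hox at 96.4. Which proteins or chromatin marks lie at these anchors was not tested, and expression in these cells was not used here.

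The 3 highest peak scores, on chromosome 4, may come from a shared floor under the background of the score. The peak pixel divided by the score was 0.025 for all 3, a ratio of highest to lowest of 1.0, against 1.49 among the next 3 loops by score. An unusually strong contact was argued against, since the highest of the 3 pixel values was at percentile 64.3 of the 10 kb loops. No biological explanation was tested.

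The low number of loops on the X chromosome has more than one candidate explanation. Gene density was argued against: chromosomes 12 and 18, within 0.2 genes per Mb of X, had 2.44 and 2.95 times its loop density. A missing 5 kb contact map for X would account for the absence of 5 kb loops but not for the rest, since X had 0.727 loops of 10 and 25 kb pixels per Mb and the lowest autosome 1.14. A lower contact depth, as a single copy of X would give, stays open. The share of 5 kb loops on X was 0, below the lowest autosome at 4.31%, but the list gives no depth per chromosome, so lower depth and a real scarcity of loops on X cannot be told apart.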
